A study of Mus musculus with 7 samples.

How the data were processed

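The data came from adult C57BL/6J mice: 4 bulk libraries of primary NSPC cultures, 2 bulk libraries of whole DG, and 1 single-cell library that mixed 3 cultures. Groups, sex and replicate names (F1, F2, M1, M2) were taken from the labels. Per the labels' protocols, about 30000 cultured cells were lysed per library, RNA of both groups was extracted with the same kit, whole DG libraries were made with a directional kit (NEBNext Ultra II Directional) and culture libraries with a full-length low-input kit (SMART-Seq HT), and all were sequenced as paired ends on an Illumina instrument. Kit and group therefore coincide, and no fit with the kit as a term is possible. The labels describe the cultures as separate, so p-values measure the spread between cultures and, for whole DG, between 2 animals.

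The bulk table holds raw gene counts as deposited by the authors, 1 whole number per gene and library, not normalized. The submitters' processing notes name CASAVA 1.8.2, HISAT2 2.0.6, Subread and featureCounts, and the human assembly GRCh38, although the gene symbols are mouse symbols. Of 50600 table entries, 47674 (94.2%) matched a symbol of the mouse annotation GENCODE M21 on GRCm38, which was used here for gene positions, lengths, GC content and overlaps. The authors' counting options, and so the use of strand and the treatment of overlapping genes and of reads shared between copies, are not given in the sources used here: 7304 of the 17586 tested genes found in the annotation (41.5%) overlap another gene, as do 24 of the 69 named genes, and their values are uncertain to that extent. The symbols held 682 entries with a repeated name and 27 turned into dates by a spreadsheet, which were kept as separate genes. The single-cell table holds natural log values deposited by the authors, the natural log of 1 plus UMIs per 10000 in the cell, with a cluster number in each cell name. Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat 3.1.0 were used, while the labels' protocol names other versions of both. The authors' cell filter is not given in the sources used here. The values ranged from 2001 to 8531 UMIs and from 738 to 2499 genes per cell, with a median mitochondrial share of 10.4% and a maximum of 37.2%.

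Bulk counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, TMM scaling, default filter on low counts, Benjamini-Hochberg adjustment, threshold 0.05) on all 6 libraries with group as the only term. Sexes were compared in the 4 cultures with the same test, and an interaction of sex and group was tested in all 6 libraries. CPM use TMM library sizes. Gene lists, 28 in number with 645 genes, of which 643 were in the table, were fixed before the data were examined, as were the tests, the naming rule and the alternatives unless said otherwise. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. The naming rule took the 5 largest changes each way among genes past the threshold, separated in every library and at 50 CPM or more in the higher group, without unnamed gene models. It then took the 2 most abundant members of each list (4 for growth factors and for cytokines), Vegfa, Xist and 4 Y-linked genes. Genes outside it are said to have been chosen after their values were seen, and some genes that the rule names are not reported here. Where a group had 0 counts, a floor of 3 counts over the group gave a lower bound of the fold, and with 1 to 3 counts the ratio has an exact counting interval. Such bounds and intervals cover counting error only, since bulk reads without molecular identifiers are not independent molecules.

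UMI counts of single cells were recovered from the natural log values with all entries (100%) within 0.01 of a whole number. Shares of cells have exact binomial (Clopper-Pearson) intervals and levels have exact Poisson intervals. Cells were thinned to 2000 UMIs, which left out 0 cells, to compare shares and levels across clusters of different depth. No cell filter was added. Doublets were not removed and no doublet caller was run. Clusters are the authors', and an own clustering (scanpy 1.11.5 with leidenalg 0.10.2, 2000 variable genes, 30 components, 15 neighbours) served as an alternative. No cluster was given a cell type name.

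On simulated counts with known changes, the comparison of cultures with whole DG recovered 37.5% of 2-fold and 69.1% of 4-fold changes with 10 false calls among 17370 genes, and the comparison of sexes 38.5%, 85.9% and 98.4% of 2-fold, 4-fold and 16-fold changes with 21 false calls among 14825 genes. Each simulation changed 200 genes, as many up as down. In the data 13976 of 18088 genes were called between cultures and whole DG, so the simulated rates do not describe that comparison. Camera called a simulated shift of the proliferation list and 1 of 27 unchanged lists. Genes were drawn independently there, so this does not test camera at the correlations estimated in the data, such as 0.622 for the proliferation list. Thinning cells reduced a simulated gap between depths from 8.21 to −0.0283 percentage points. The alternatives were other scalings, no filter or a stricter one, a fold above 2, sex as a term, a block on the replicate name, mitochondrially encoded genes left out, genes detected in both groups, length and GC trends removed (mgcv 1.9.3), each library left out in turn, DESeq2 1.42.0 and limma-voom. Relative to the main scaling, the median log2 difference of all genes moved by −0.102 with DESeq2's size factors, by −0.143 with the DESeq2 test and by 0.182 with upper quartile factors, and it moved by 0.139 with the stricter filter and by 0.153 over genes detected in both groups. No change of scaling moved the share of higher genes among those called, 46.1%, by more than 10 percentage points. Gene-level statistics were summarised with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.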

Results

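Neural stem and progenitor cells (NSPCs) persist in the dentate gyrus (DG), the hippocampal region where granule neurons are born in the adult mouse, and can be expanded as adherent cultures in serum-free medium with epidermal growth factor and fibroblast growth factor 2 at 20 ng/ml each. Transcripts were counted by bulk RNA sequencing in 4 primary NSPC cultures at passages 6 to 15 (females F1 and F2, males M1 and M2) and in whole DG tissue of 2 mice (female F1, male M2). A single-cell library held a mixture of 3 cultures, 2 female and 1 male, which cannot be told apart by sample. The deposited gene counts summed to between 9917697 and 11747408 per culture library and to 16676618 and 17351636 in the whole DG libraries. Across genes, which are not independent replicates, Spearman's rho lay between 0.975 and 0.983 for pairs of cultures, was 0.993 for the whole DG pair, and lay between 0.564 and 0.588 for a culture against a whole DG library. The cultures and the tissue were prepared with different library kits, so that kit and group cannot be told apart in any comparison of these groups by counts alone.

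The first comparison asked how NSPCs grown in culture differ from the tissue they were taken from. Transcripts of the cell division machinery and of several secreted factors were far higher in the cultures, and transcripts of neurons and of vascular and immune cells were far lower. Angpt2, which encodes angiopoietin 2, a secreted ligand of the endothelial receptor Tie2, had the largest rise that the naming rule picked: 13408 counts in the 4 cultures together against 10 in the 2 whole DG libraries, a log2 difference of 9.86 (SE 0.61, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 2.28e-06). The replication licensing factor Cdc6 reached 50.3 ± 6.45 counts per 1000000 (CPM; mean ± SD, n = 4 cultures and n = 2 whole DG libraries throughout) in cultures with 2 counts in the whole DG libraries together, a ratio of 803 (95% counting interval 222 to 6636). The mitotic kinase Melk reached 68.9 CPM with 3 counts in whole DG, a ratio of 736 (252 to 3572). The imprinted gene Peg12 was at 104 ± 14.5 against 0.188 ± 0.00792 CPM, and the cyclin-dependent kinase Cdk1 at 188 ± 47.8 against 0.503 ± 0.110 CPM, log2 differences of 9.04 and 8.53 (edgeR adjusted p = 1.39e-07 and 7.78e-07). On the mouse assembly GRCm38, Angpt2 lies on chromosome 8 from 18690263 to 18741562 and Cdk1 on chromosome 10 from 69335146 to 69352938.

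The 5 largest falls that the naming rule picked were of transcripts at or near 0 counts in the cultures. Rnf112, a neuronal RING finger protein, and Cpne6, a calcium-binding copine of excitatory neurons, were at 755 ± 216 and 628 ± 92.1 CPM in whole DG with 0 counts in all 4 cultures. Against a floor of 3 counts over the group, they were at least 11170-fold and 9285-fold lower in the cultures. Trank1 (437 CPM in whole DG) and Srcin1 (299 CPM), a regulator of Src kinase at synapses, were also at 0 counts in every culture, at least 6454-fold and 4415-fold lower. Ddn, which encodes the dendritic protein dendrin, had 2779 ± 73.3 CPM in whole DG and 2 counts in the cultures together, both in F2 and 0 without it, a ratio of 61670 (17070 to 509200). Ddn lies on chromosome 15 from 98803777 to 98809490 and overlaps a gene on the opposite strand.

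Of 18088 genes tested, 13976 passed an adjusted p of 0.05, with 6440 higher and 7536 lower in the cultures. At least 8-fold differences were found for 1128 higher and 3748 lower genes. When the test asked for a fold above 2, the higher genes numbered 3671 and the lower ones 5772. Among the 10282 tested genes that overlap no other annotated gene, 8055 passed, 3728 higher and 4327 lower, which matters because strand use in counting is not given in the sources used here.

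All 33 tested members of the proliferation list rose in the cultures, with a median log2 difference of 5.30 (camera adjusted p = 1.53e-12; adjusted p = 0.334 with an estimated correlation). Ccnd1, the G1 cyclin D1, was at 931 ± 165 against 41.9 ± 6.90 CPM, and its partner kinase Cdk4 at 624 ± 69.0 against 58.1 ± 3.58 CPM, log2 differences of 4.47 and 3.42 (edgeR adjusted p = 1.19e-06 and 7.70e-07). Of 28 neural stem and progenitor genes, 15 rose and 11 fell, and the list did not pass as a set (camera adjusted p = 0.191). Slc1a3, the glutamate transporter GLAST of radial glia-like cells, rose by a log2 difference of 1.63 (SE 0.24, edgeR adjusted p = 0.000345), and the cyclin Ccnd2 by 3.55 (SE 0.29, edgeR adjusted p = 9.84e-06). The intermediate filament gene Nes, chosen after its values were seen, was at 1216 ± 218 against 9.74 ± 0.189 CPM. In the opposite direction, also chosen after their values were seen, the transcription factor Sox2 was at 6.11 ± 1.18 against 36.3 ± 0.910 CPM, and Gfap, the intermediate filament of astrocytes and radial glia-like stem cells, was at 2.21 against 425 CPM. The fall of Sox2 was not seen in the single cells, where it stood at 168 UMIs per 1000000. That number is above its CPM in whole DG, but the 2 assays do not share a scale for single genes.

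Neuronal lists fell. All 30 mature neuron and synapse genes were lower in the cultures (camera adjusted p = 4.94e-09; adjusted p = 0.148 with an estimated correlation). Camk2a, the alpha subunit of the synaptic kinase CaMKII, was at 1.55 ± 0.219 against 4666 ± 107 CPM, and the beta subunit gene Camk2b at 199 ± 22.9 against 2138 ± 133 CPM. Of 14 genes of inhibitory interneurons, 13 fell and 1 rose (camera adjusted p = 0.00018; adjusted p = 0.148 with an estimated correlation). Gad1, which makes GABA, fell by 6.18 on the log2 scale (SE 0.19, edgeR adjusted p = 1.00e-07). Of 20 neuroblast and immature neuron genes, 14 fell and 4 rose (camera adjusted p = 0.0217; adjusted p = 0.200 with an estimated correlation). The neuroblast microtubule gene Dcx, chosen after its values were seen, was at 0.0239 CPM, a single count, against 21.9 CPM.

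Markers of other cell types of the tissue fell as well. All 20 microglial genes were lower (camera adjusted p = 1.91e-07; adjusted p = 0.148 with an estimated correlation), with a median log2 difference of −8.09 when genes at 0 counts stand at their bound. Among them the receptor gene Csf1r fell by 2.98 on the log2 scale (SE 0.18, edgeR adjusted p = 1.97e-06). Of 18 endothelial genes, 17 fell (camera adjusted p = 0.000514; adjusted p = 0.148 with an estimated correlation). Slco1c1, a transporter of the blood-brain barrier, was at 1.35 ± 1.19 against 44.7 ± 0.555 CPM. Of 14 myelin genes, 11 fell and none rose (camera adjusted p = 0.00272; adjusted p = 0.332 with an estimated correlation), with a median of −6.36 with genes at 0 counts at their bound. Mbp, myelin basic protein, fell from 602 ± 69.1 to 0.120 ± 0.144 CPM (log2 −12.26, −13.09 without culture M1). Of 9 choroid plexus, ependymal and blood genes, 7 fell and 1 rose (camera adjusted p = 0.0161; adjusted p = 0.200 with an estimated correlation). The haemoglobin gene Hbb-bs had 58.2 CPM in whole DG and 1 count in the cultures, in F2 and 0 without it, a ratio of 2579 (462 to 101900), and Hba-a1 fell by 8.31 on the log2 scale (−9.95 without culture M1), although reads of haemoglobin genes may be shared with near-identical copies.

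Astrocyte, oligodendrocyte precursor and mural cell lists held members that moved in opposite directions. Of 19 astrocyte genes, 11 fell and 3 rose (camera adjusted p = 0.110): the glutamate transporter gene Slc1a2 was at 19.6 ± 8.61 against 2307 ± 287 CPM and the glutamine synthetase gene Glul at 68.9 ± 27.2 against 1473 ± 75.6 CPM. Of 11 oligodendrocyte precursor genes, 7 fell and 2 rose (camera adjusted p = 0.191). Olig1, a transcription factor of the oligodendrocyte lineage, was at 2456 ± 685 against 74.0 ± 11.8 CPM (log2 5.05, SE 0.34, edgeR adjusted p = 3.61e-06), and the proteoglycan gene Cspg4 rose by 2.70 (SE 0.46, edgeR adjusted p = 0.000829). In the same list Cspg5 fell by 3.06 on the log2 scale (SE 0.29, edgeR adjusted p = 2.64e-05). Pdgfra and Sox10, chosen after their values were seen, were at 2.69 against 53.6 and at 0 against 19.5 CPM. Of 17 mural cell and fibroblast genes, 13 fell and 2 rose (camera adjusted p = 0.0710). That list passed without culture F2 (adjusted p = 0.0214), without culture M2 (0.0427) or without whole DG M2 (0.0447), and with no filter on low counts (0.0185), within a range of 0.0185 to 0.313 over its camera alternatives, and fry, which tests another hypothesis, gave 7.45e-05.

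**Figure D1:**
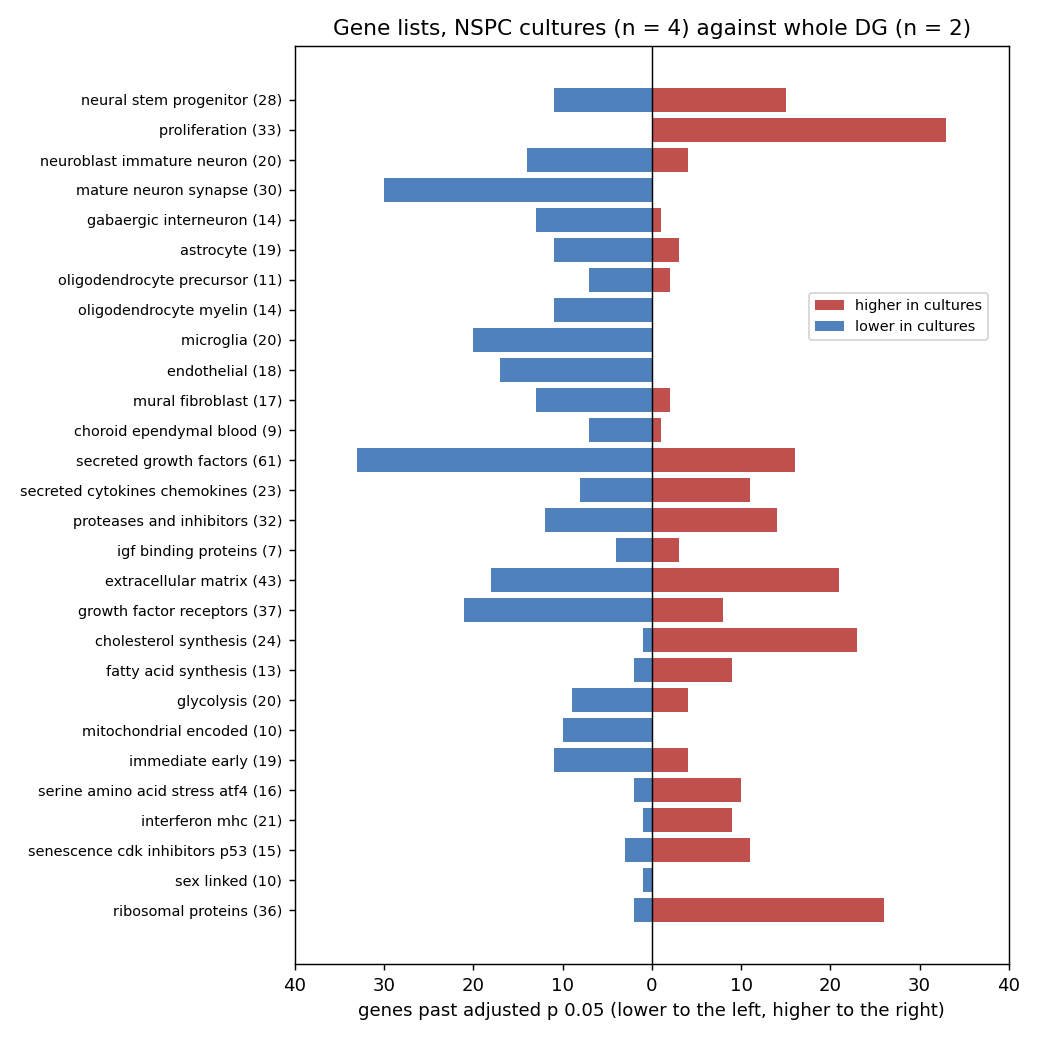
Number of genes per list that passed an edgeR adjusted p of 0.05 in 4 NSPC cultures against 2 whole DG libraries, with lower genes to the left and higher genes to the right of 0 and the number tested in brackets. All 33 proliferation genes lie to the right, and all 30 mature neuron and all 20 microglial genes lie to the left.

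Genes of lipid and amino acid synthesis were higher in the cultures. Of 24 cholesterol synthesis genes, 23 rose and 1 fell (camera adjusted p = 1.17e-06; adjusted p = 0.373 with an estimated correlation). Sqle, the epoxidase that commits squalene to sterols, was at 780 ± 114 against 55.6 ± 6.42 CPM (log2 3.81, SE 0.20, edgeR adjusted p = 1.12e-06), and Hmgcs1, an early enzyme of the pathway, at 772 ± 141 against 203 ± 29.5 CPM. Of 13 fatty acid synthesis genes, 9 rose and 2 fell (camera adjusted p = 0.0208; adjusted p = 0.313 with an estimated correlation), among them the desaturase gene Scd2, at 2502 ± 143 against 1007 ± 78.0 CPM. Of 16 serine synthesis and amino acid response genes, 10 rose and 2 fell (camera adjusted p = 0.0208; adjusted p = 0.550 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, rose by 3.31 (SE 0.21) and the amino acid transporter gene Slc3a2 by 2.52 (SE 0.17; edgeR adjusted p = 2.69e-06 and 3.77e-06). Of 20 glycolysis genes, 4 rose and 9 fell (camera adjusted p = 0.571), and the 2 most abundant both rose: Pkm, pyruvate kinase, by 1.58 and Eno1, enolase 1, by 2.40 (edgeR adjusted p = 0.000204 and 3.45e-06).

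Of 15 genes of the p53 response and of cyclin-dependent kinase inhibitors, 11 rose and 3 fell (camera adjusted p = 0.00284; adjusted p = 0.148 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 711 ± 98.8 against 9.05 ± 1.62 CPM (log2 6.30, SE 0.24, edgeR adjusted p = 2.26e-07), and the p53 target Ccng1 at 602 ± 128 against 67.4 ± 9.04 CPM. Of 21 interferon and MHC genes, 9 rose and 1 fell (camera adjusted p = 0.0710), with Ifitm3, an antiviral membrane protein, higher by 4.72 (SE 0.48, edgeR adjusted p = 3.83e-05). The interferon list passed without culture F2 (adjusted p = 0.0366) or without culture M2 (0.0244), with no filter on low counts (0.0300) and with whole DG thinned to the depth of the cultures (0.0359), within a range of 0.0244 to 0.661 over its camera alternatives. Of 19 immediate-early genes, 11 fell and 4 rose (camera adjusted p = 0.148), with Egr1, an activity-induced transcription factor, higher by 1.93 (SE 0.38, edgeR adjusted p = 0.00177). All 10 tested mitochondrially encoded genes fell (camera adjusted p = 0.0159; adjusted p = 0.373 with an estimated correlation). They had few reads in both groups: mt-Co1 was at 1.26 ± 0.448 against 10.4 ± 0.924 CPM and mt-Cytb at 1.55 ± 0.654 against 6.51 ± 0.0801 CPM, whereas mt-Co1 stood at 8085 UMIs per 1000000 in the single cells. Of 36 ribosomal protein genes, 26 rose and 2 fell (camera adjusted p = 0.000514; adjusted p = 0.610 with an estimated correlation), with reads that may be shared with processed pseudogenes.

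Counts of list members adjusted over the list alone equalled those over all genes tested in every list except interferon and MHC, where 8 rather than 9 members rose. In all, 14 of 28 lists passed camera with its preset correlation, 6 higher and 8 lower, and 0 passed with an estimated correlation, where 7 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether a list moves on balance in one direction, passed 24 lists.

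Several named genes differed by about 2-fold or less, and calls for them rested on few libraries. Vegfa, the vascular growth factor, was lower in the cultures, 28.0 ± 4.36 against 44.4 ± 1.14 CPM (log2 −0.67, SE 0.17, edgeR adjusted p = 0.00672), and lost the call without whole DG M2 (adjusted p = 0.0549; range 0.000552 to 1 over 21 alternatives). The adhesion molecule gene Ncam1 rose by 0.47 and lost the call without whole DG F1 or M2 (adjusted p = 0.138 and 0.0936; range 0.00226 to 1). Ncam1 also lost it with DESeq2's size factors (0.0617), with DESeq2 (0.0624), with a stricter filter on low counts (0.0621) and in the 4 libraries named F1 or M2 (0.0731). Stmn1, a tubulin-binding protein of dividing and young neural cells, rose by 0.89 and lost the call without whole DG M2 (adjusted p = 0.0513; range 0.00141 to 0.591). Ntrk2, the receptor of brain-derived neurotrophic factor, fell by 0.85 on the log2 scale, lost the call without whole DG F1 (adjusted p = 0.0669; range 0.000401 to 0.648) and stood at 0.30 with gene length and GC trends removed. Fasn, fatty acid synthase, rose by 0.77 and lost the call without whole DG F1 (adjusted p = 0.0567; range 3.75e-05 to 0.877). The MHC light chain gene B2m rose by 0.92, lost the call without whole DG F1 or M2 (adjusted p = 0.0850 and 0.103; range 0.00162 to 0.515) and stood at −0.28 with length and GC trends removed.

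Rpl4 rose by 0.44 and lost the call without culture F1 (adjusted p = 0.0523) or without whole DG F1 or M2 (0.135 and 0.129; range 0.00538 to 1). Rpl4 also lost it with DESeq2's size factors (0.0844), with DESeq2 (0.0914) and with a stricter filter on low counts (0.0697). It stood at −0.051 with length and GC trends removed. Jun passed narrowly, falling by 0.51 on the log2 scale (edgeR adjusted p = 0.0451), and lost the call without F1, M1 or M2 of the cultures (adjusted p = 0.0804, 0.0876 and 0.0933) or without whole DG F1 or M2 (0.121 and 0.161; range 0.00282 to 1). It also lost the call with upper quartile factors (0.140), with length and GC trends removed (0.139) and with whole DG thinned (0.0559). Not past the threshold were the glucose transporter gene Slc2a1 (log2 −0.10, adjusted p = 0.736), Rpl3 (0.30, adjusted p = 0.0845; 0.0386 without culture M1, 0.0113 with upper quartile factors and 0.0329 in the 4 libraries named F1 or M2; range 0.0113 to 1) and the iron carrier gene Trf (1.799, adjusted p = 0.0636; 0.0179 without culture F2, 0.0394 without M2, 0.0487 with upper quartile factors and 0.00964 in the same 4 libraries; range 0.00209 to 0.255), whose log2 difference was 0.90 without culture M1. None of Vegfa, Ncam1, Stmn1, Ntrk2, Fasn, B2m, Rpl4 and Jun, nor Mif, Csf1 and Ddx3x, passed when the test asked for a fold above 2.

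The series asks which secreted factors adult NSPCs make, and transcripts of 198 secreted, protease and matrix genes were therefore ranked within the cultures. Serpine2, a secreted inhibitor of thrombin and plasminogen activators, was the most abundant at 5368 ± 1174 CPM (SD, n = 4), followed by Igfbp2, an insulin-like growth factor binding protein, at 2175 ± 1098, and Tnc, the matrix glycoprotein tenascin C, at 1636 ± 1174. Ptn, the heparin-binding growth factor pleiotrophin, was at 1155 ± 324, the protease gene Ctsd at 839 ± 233 and Igfbp4 at 708 ± 441 CPM. The place of Tnc rested on the female cultures, at 2111 and 3071 CPM against 574 and 788 CPM in the males, and without F2 its mean of 1158 CPM fell below that of Ptn, 1287 CPM. Divided by exon length, Igfbp2 came first and Serpine2 next, at 1178 and 648 CPM per kilobase, and Tnc moved from rank 3 to rank 8. In single cells Ptn, at 2781 UMIs per 1000000, and Igfbp2, at 2123, exceeded Serpine2, at 1499. Of the 198, 80 reached 10 CPM in the cultures and 85 in whole DG, 57 in both, and 1 of the 10 most abundant was shared between the groups.

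Of the 166 secreted and matrix genes tested against whole DG, 65 were higher and 75 lower in the cultures. Log2 differences were 5.42 for Serpine2, 7.12 for Igfbp2, 6.99 for Tnc, 2.77 for Ptn, 1.44 for Ctsd and 4.30 for Igfbp4, all past the threshold, with edgeR adjusted p between 1.11e-06 for Serpine2 and 0.00107 for Ctsd. Of 61 growth factor genes, 16 rose and 33 fell (camera adjusted p = 0.189). Clu, the chaperone clusterin, fell by 3.69 on the log2 scale (SE 0.83, −4.65 without culture F2, edgeR adjusted p = 0.00355; 0.0574 with no filter on low counts, range 4.995e-06 to 0.0574), and Fgf13, an intracellular fibroblast growth factor homologue of neurons, by 5.85 (SE 0.25, edgeR adjusted p = 3.87e-07). Of 23 cytokine and chemokine genes, 11 rose and 8 fell (camera adjusted p = 0.571). Cx3cl1, the neuronal chemokine fractalkine, fell by 1.63 on the log2 scale, and Mif, Kitl and Csf1 rose by 1.31, 1.79 and 0.89 (edgeR adjusted p = 0.000190, 0.000854, 0.00269 and 0.000604). Of 32 proteases and inhibitors, 14 rose and 12 fell (camera adjusted p = 0.400), and of 43 matrix genes, 21 rose and 18 fell (camera adjusted p = 0.400), among them Sparcl1, which fell by 3.55 on the log2 scale. Of 7 insulin-like growth factor binding proteins, 3 rose and 4 fell (camera adjusted p = 0.983). Of 37 growth factor receptor genes, 8 rose and 21 fell (camera adjusted p = 0.229), with the pleiotrophin receptor gene Ptprz1 higher by 2.02 (SE 0.22, edgeR adjusted p = 6.02e-05). The median and the mean had opposite signs for proteases (0.43 and −0.13), matrix genes (0.72 and −0.27) and binding proteins (−2.89 and 0.34), with camera's direction upward in all 3 lists. For binding proteins it was downward without culture M1, without whole DG M2 and with whole DG thinned (camera adjusted p = 0.962, 0.985 and 0.996, all past no threshold). For cytokines camera gave an upward direction, and fry, and camera with no filter on low counts, a downward one.

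**Figure D2:**
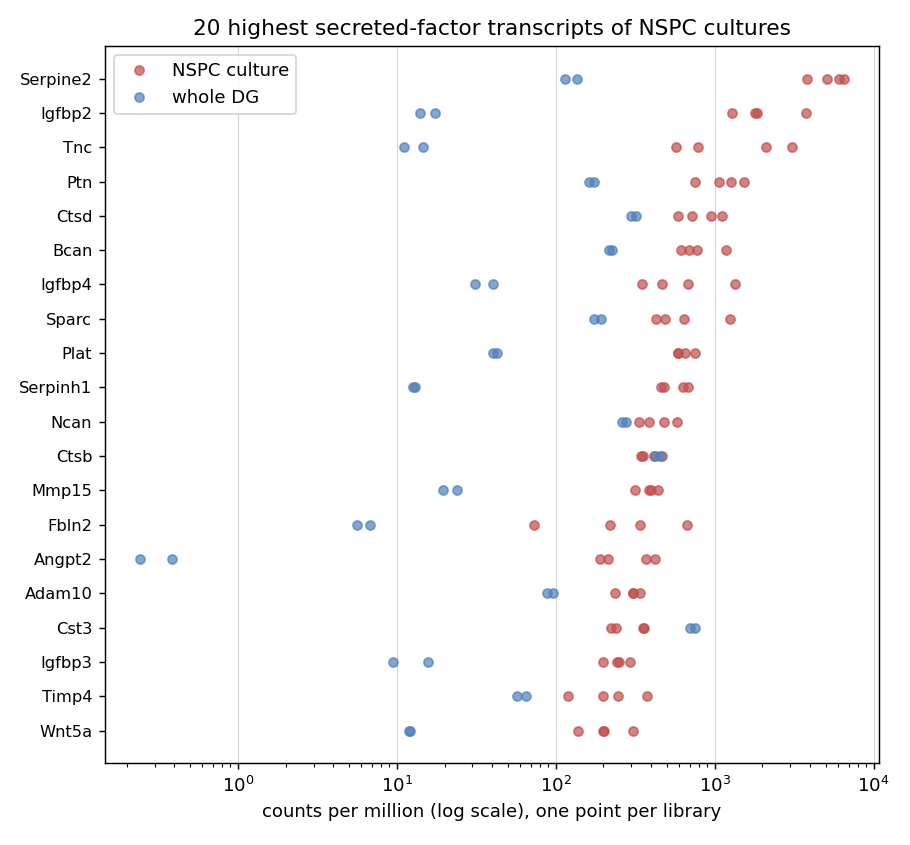
CPM on a log axis of the 20 secreted, protease and matrix genes with the highest mean in 4 NSPC cultures, 1 point per library, with the 2 whole DG libraries in blue. Serpine2 averaged 5368 CPM in the cultures and 126 CPM in whole DG, while Cst3 averaged 294 and 729 CPM.

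The cultures came from mice of both sexes, and male cultures were compared with female ones. In edgeR's test of all 4 cultures with the default filter, only sex-linked genes passed: Xist, the RNA that silences an X chromosome, had 689 counts in the female cultures and 0 in the male ones, at least 201-fold higher in females (edgeR adjusted p = 0.0195). The Y-linked genes Ddx3y (log2 7.98, SE 0.34, edgeR adjusted p = 0.00289; counting ratio 268, interval 104 to 986), Eif2s3y (ratio 1370, interval 245 to 54160; adjusted p = 0.0195) and Uty (at least 218-fold; adjusted p = 0.0195) were higher in males. Kdm5d, also Y-linked, had 380 counts in males and 0 in females, at least 144-fold, with an edgeR adjusted p of 0.105. Uty lost the call without M1 or M2, and Kdm5d gained it without F1 or F2. Such fits leave 1 culture of a sex and take the spread from the other sex alone. Over all alternatives the adjusted p ran from 4.32e-53 to 0.387 for Uty and from 7.06e-38 to 0.426 for Kdm5d. These were 4 of 15140 genes tested, and 942 genes had an unadjusted p under 0.05 where 757 would by chance. DESeq2 passed 53 genes, 46 of them outside the sex-linked list, and edgeR with no filter on low counts 273, 265 of them outside it. With limma-voom 0 genes passed and 949 had an unadjusted p under 0.05, with adjusted p of 0.0721 for Xist, 0.0870 for Ddx3y and 0.258 for Eif2s3y. Their ranges over the alternatives were 9.45e-53 to 0.556, 9.23e-70 to 0.363 and 1.49e-90 to 0.356. With whole DG libraries in the fit 0 genes passed, with 1734 at an unadjusted p under 0.05. The count was 81 without F1 and 13 without F2, each leaving 1 female culture, of which 75 and 7 were outside the sex-linked list, and 4 without M1, 1 of them outside it, and 3 without M2. Of the sex-linked list, 1 of 10 genes, Ddx3x, differed between cultures and whole DG, falling by 1.01 on the log2 scale (edgeR adjusted p = 0.000897; camera adjusted p = 0.912), and Xist stood at −4.22 (SE 1.86, adjusted p = 0.0672), at −4.26 and past the threshold with sex as a term (adjusted p = 2.89e-06), at 4.56 without whole DG F1 and at −5.23 without whole DG M2 (adjusted p = 0.248 and 0.0235; range 2.89e-06 to 0.528). Whether the effect of culture differs between the sexes stayed open: edgeR's interaction test passed 0 of 19100 genes, with 338 at an unadjusted p under 0.05 where 955 would by chance. The design had 1 whole DG library per sex, the power of this test was not simulated, and no other tool was run for it.

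The single-cell library was used to see whether the abundant transcripts were spread over the cells or held by some of them. It held 14912 cells with a median of 4048.5 unique molecular identifiers (UMIs) and 1712 genes per cell, in the 6 clusters the authors deposited. Cluster 0 (26.3% of cells) was led by Thrsp, Mxd4, Mt3, Ccnd2 and Sox4, cluster 1 (22.1%) by Cenpa, Arl6ip1, Tubb4b, Hmgb2 and Ube2s, and cluster 2 (21.9%) by Pclaf, Top2a, Hmgb2, Hist1h2ap and Dek. Cluster 3 (12.8%) was led by the replication genes Mcm3, Slbp, Hells, Mcm6 and Nasp, cluster 4 (9.58%) by the mitotic genes Ube2c, Cenpf, Top2a, Prc1 and Ccnb1, and cluster 5 (7.32%) by Eif4ebp1, Atf5, Malat1, Asns and Fth1. With 1 library there was no test between clusters, and intervals below are exact 95% intervals for counting error alone.

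Ptn was detected in 99.96% of cells (interval 99.91 to 99.99%), Igfbp2 in 98.9% (98.7 to 99.1%) and Serpine2 in 98.9% (98.8 to 99.1%). After thinning every cell to 2000 UMIs the shares were 99.3%, 95.1% and 92.6%. Slc1a3 was detected in 91.9%, Olig1 in 95.3% and Cdkn1a in 82.4% of cells (74.5%, 82.2% and 65.2% after thinning). Tnc was detected in 46.0% (27.3% thinned), Angpt2 in 22.7% (12.0%) and Vegfa in 4.14% (2.10%). Genes of other types differed in their shares. Camk2a had a UMI in 0.288% of cells, Pdgfra in 0.248%, Gfap in 0.215% and Pecam1, an endothelial adhesion molecule, in 0.141%, and Dcx, Mbp, C1qa and Sox10 were not among the 15536 genes listed. Of the endothelial genes 13 were listed, none of them in over 10% of cells, whereas 9 of 18 listed astrocyte genes and 5 of 24 listed mature neuron genes were in over 10% of cells, and 3 of 8 listed oligodendrocyte precursor genes in over 50%. No other cell type was in the library to give a background share for free RNA. The mixed sexes bear on Xist alone, which met a Y-linked UMI in 2.09% of cells, where independent detection would give 9.30%. That 2.09% is a share of all cells, of which 15.93% had a Y-linked UMI, so it is not the background share of Xist in male cells. All shares are of cells with a UMI, and the background of the other genes is unknown. Cells with a Mki67 UMI, a marker of cycling cells chosen here after its values were seen, made up 38.5% (24.9% thinned).

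By cluster, after thinning, Ptn ranged from 2438 UMIs per 1000000 (UMI CPM; 2373 to 2505) in cluster 5 to 3247 (3207 to 3287) in cluster 0, Igfbp2 from 1783 to 2652 and Serpine2 from 1178 to 1877, with the extremes of all 3 in the same clusters. Tnc was highest in cluster 5, at 286 UMI CPM (264 to 309) against 136 (127 to 145) in cluster 1. Cells with an Xist UMI made up 59.7% of cluster 5 and 36.1% of cluster 1, and those with a Y-linked UMI 5.86% and 11.2%. Tnc was higher in the female bulk cultures than in the male ones, so cluster and culture of origin cannot be told apart for it. Vegfa was also highest in cluster 5, at 22.0 (16.2 to 29.1) against 7.70 (4.83 to 11.7) in cluster 4. Ctsd reached 337.5 (313.5 to 363) in cluster 5 and 165 (151 to 181) in cluster 4. Angpt2 lay between 56.6 (51.0 to 62.7) in cluster 2 and 88.4 (76.3 to 102) in cluster 5, and Clu was highest in cluster 0, at 20.2 (17.2 to 23.7). Cdkn1a was lowest in cluster 3, at 438.5 (418 to 460), and highest in cluster 2, at 919 (896 to 942).

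**Figure D3:**
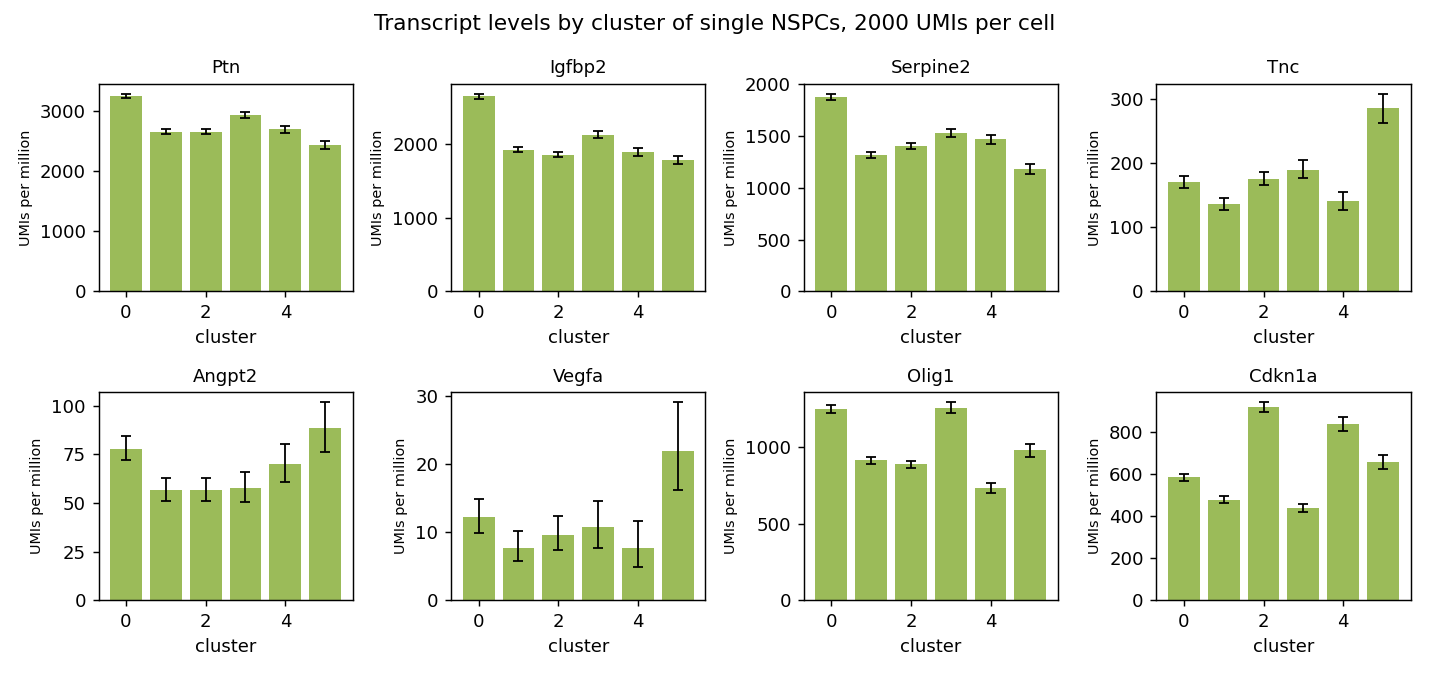
UMI CPM of 8 genes in the 6 clusters of single NSPCs, each cell thinned to 2000 UMIs, with bars for the cluster and lines for exact 95% Poisson intervals that cover counting error only. Tnc and Vegfa are highest in cluster 5, at 286 and 22.0 UMI CPM, and Ptn, Igfbp2 and Serpine2 in cluster 0. The clusters differed in their shares of cells with Xist and with Y-linked UMIs.

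The same kind of culture was measured by both assays, and levels were compared across 13756 genes, which are not independent replicates. Bulk cultures and single cells correlated with Spearman's rho 0.798 and Pearson's r 0.792 on the log2 scale, and whole DG and single cells with 0.487 and 0.480. Igfbp2, Cdk1 and Cdkn1a, chosen after their values were seen, were nearly level, at 2123, 184 and 668 UMI CPM against 2175, 188 and 711 CPM, and Olig1 was at 997 against 2456. After a small constant was added to both levels, they lay within 4-fold of each other for 80.4% of genes. On that scale 67 genes were at least 16-fold higher in single cells and 185 at least 16-fold higher in the bulk cultures. The constant shrinks folds at low levels, so genes low in both assays count as within 4-fold.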

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

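The tests of an oligodendrocyte precursor fraction and of damage, sex and depth in cluster 5 were chosen only after the results they bear on were seen, as was the thinning of the whole DG libraries, and the test of GC content was chosen after some of the genes it covers had been seen, though not their GC content. In 3 of 70 measures examined, which were 69 named genes and the total count, 1 culture lay apart from the other 3, where about 3.5 would by chance. Cdk4 was at 520.5 CPM in culture M1 against 650 to 662 in the others. Ddn was at 0.173 CPM in culture F2 and Hbb-bs at 0.0867 CPM in culture F2, each against 0 in the others, which are 2 counts and 1 count.

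The split of 13976 genes between cultures and whole DG coincides with the library kit, and 10x single cells, a different chemistry applied to cultures of the same kind, gave levels made with neither kit, although the genes compared were called and matched with levels from both. Genes at least 8-fold lower in the bulk cultures lay below uncalled genes of the same whole DG level in single cells. The median log2 ratio was −2.17 over 3000 genes (interval −2.29 to −2.04). Genes at least 8-fold higher lay above uncalled genes, by 3.18 over 749 genes (3.06 to 3.34). Both intervals come from 1000 resamples, and genes are not independent replicates. The bulk test called 3748 lower and 1128 higher genes of that size. Those outside the 3000 and 749 did not enter the ratios and are not covered by them. The planned test set no lower limit on CPM, but it was first run with one of 10 CPM in the higher group, so that ratios of −3.15 and 3.43 were seen before those without a limit. For the genes compared, the ratios without a limit argue against a bias particular to the culture kit as the whole cause. A bias shared by the culture kit and 10x could give such ratios and was not tested. Of the calls, 89.3% were kept with their direction when length and GC trends were removed, which argues against these trends. With whole DG thinned to the depth of the cultures 97.55% were kept, which argues against depth alone. A difference between cultured cells and tissue remains a hypothesis, and for 125 of the 2040 lower genes at 10 CPM or more in whole DG the single-cell level reached that of uncalled genes, and whether the culture kit lost their transcripts through high GC content cannot be told apart from other causes, since their median GC content differed from that of the others by 0.021 percentage points with an interval of −2.17 to 2.81.

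Olig1 rose in the cultures while Sox10 had 0 counts there, and Olig2 stood at 24.9 against 21.6 CPM. A fraction of oligodendrocyte precursor cells that carry Pdgfra or Sox10 is argued against by both assays. In the bulk cultures Pdgfra stood at 2.69 against 53.6 CPM. In single cells 0.257% (0.177 to 0.361%) of those with an Olig2 UMI had a Pdgfra UMI, against 0.192% of the others, and Sox10 was not among the genes listed. Of 11 precursor genes tested, 7 fell and 2 rose, and Cspg4, at 121 against 18.6 CPM, rose with Olig1. Precursor cells without Pdgfra and Sox10 are therefore not covered. How far free RNA spread Olig2 over 86.0% of the cells cannot be told apart from expression, since 63.73% of cells had 2 or more Olig2 UMIs and an even spread at the same level, computed after the values were seen, would give 66.46%. Expression by many of the cultured NSPCs may underlie the Olig1 and Olig2 transcripts, which stays a hypothesis. Effects of culture conditions or of cells selected by culture were not tested.

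Cluster 5 of the single cells, 7.32% of cells, had the highest levels of Tnc and Vegfa and was led by genes of the amino acid response such as Asns and Atf5. Damaged cells with a raised mitochondrial share are argued against by the ratio of median shares, 1.02 against the other cells. Low depth is argued against by the ratio of median UMIs, 1.01. Other signs of damage or stress were not tested, and Malat1 and Fth1 were also among the leading genes of the cluster. In cluster 5 the share of cells with a Y-linked UMI was 0.622 times that of other cells (interval 0.488 to 0.793). After thinning, Xist was in 59.7% of cluster 5 cells and in 47.2% of all cells, so both markers leaned toward the female cultures. Whether sex, culture of origin or the level of these markers underlies this stays open, since a single male culture was mixed in. The level of Tnc, higher in the female bulk cultures, cannot be told apart from this lean. No biological explanation was tested, because the library gives no groups.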

How the results depend on the processing

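The thinning of whole DG libraries, the removal of repeated and date-like symbols, the unpaired fit of 4 libraries and the own clustering at a resolution of 0.5 were chosen after the data were seen. Calls between cultures and whole DG numbered 11815 to 14038 when 1 library was left out (with 1 whole DG library, the lone sample is assumed to vary like the cultures), and 3671 genes were higher with a fold above 2, as a stricter question must give fewer. Whether the replicate names shared by F1 and M2 pair samples of the same animals is not stated, and the correlation of deviations (0.0592 over 2 pairs) cannot tell: the block gave 13677 calls against 14288 for the same 4 libraries without it, with Ncam1 not past the threshold (adjusted p = 0.0996, and 0.0731 without the block) and Trf past it (0.00209 and 0.00964). Of 69 named genes, 53 kept direction and side of the threshold in the 19 to 21 alternatives that gave each a value. Slc2a1, never past the threshold, changed sign with upper quartile factors (0.079), the block (0.0999), the same libraries unpaired (0.13), without culture M1 (0.050) and without whole DG F1 (0.011), within −0.31 to 0.050 with 1 library left out, and Ntrk2 (0.30), B2m (−0.28) and Rpl4 (−0.051) with length and GC trends removed; Xist ran from −5.23 without whole DG M2, the male tissue, to 4.56 without whole DG F1, the female tissue, and passed with sex as a term (adjusted p = 2.89e-06) and with the block (1.25e-05). Of 28 lists, 0 passed with an estimated correlation (7 at an unadjusted p under 0.05) and 24 with fry, which tests another hypothesis. Between sexes, 4 genes became 273 with no filter on low counts (265 outside the sex-linked list), 53 with DESeq2 (46 outside it), 0 with limma-voom (949 at an unadjusted p under 0.05) and 0 in all 6 libraries (1734), and 3 to 81 with 1 culture left out; the cause was not tested. Secreted genes at 10 or more fell from 80 to 48 per kilobase of exon, where division by length lowers genes longer than 1 kilobase and raises shorter ones, such as Timp1 from 9.79 to 11.02. Own clustering gave 4, 7 and 12 clusters at resolutions of 0.3, 0.5 and 1.0, where resolution sets the number. The adjusted Rand index with the authors' clusters, a measure of shared grouping, was 0.559, 0.625 and 0.429, so the authors' grouping was matched only in part. Over 11859 genes at 1 CPM or more in both groups, rho fell from 0.798 to 0.739 for cultures and from 0.487 to 0.432 for whole DG; the cause was not tested. Among comparisons of a named gene between cultures and whole DG with an alternative, 1373 stayed, 39 lost and 11 gained a call, and 9 changed sign; among shares of single cells with a gene, 21 stayed and 150 moved, and 50 culture levels stayed. Depth limits genes near the floor, about 0.0676 CPM in cultures and 0.0940 in whole DG.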

Other observations

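The genes and counts below were chosen after their values were seen, and the values come with no test between assays. Cell cycle inhibitors and cycling markers were found in the same single cells. Cdkn1a had a UMI in 71.7% of cells with Mki67 and 63.1% of other cells after thinning to 2000 UMIs, and Cdkn2a, which encodes the inhibitors p16 and p19, in 34.0% and 34.9%. In the bulk cultures Cdkn2a was at 11.2 CPM against 0.0323, a single count, in whole DG, and Gdf15, a stress-induced secreted factor, at 26.8 against 0.186 CPM. Of 16 serine synthesis and amino acid response genes, 14 had their highest level in cluster 5, as had 11 of the 13 that lead no cluster, with Psat1 and Sesn2 as the exceptions, and 34 of 36 ribosomal protein genes were highest there too. Phgdh was at 690.5 UMIs per 1000000 (UMI CPM; 656 to 726) in cluster 5 and between 427 and 480 elsewhere.

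Some transcripts stood far apart between the assays of cultured cells. Sox2 was at 168 UMI CPM in single cells and 6.11 CPM in the bulk cultures, Olig2 at 569 and 24.9, Cdkn2a at 219 and 11.2, Jund at 106.5 and 0.636, and H1fx at 101 and 0.251. Xist was at 492 UMI CPM in the mixed single cells and 14.55 CPM over the female and male bulk cultures. Mitochondrially encoded genes took a median of 10.4% of UMIs per cell, while together they reached 6.64 CPM in the bulk cultures, with mt-Co1 at 8085 UMI CPM and 1.26 CPM.

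The protocadherin gamma cluster on chromosome 18, from 37661793 to 37841873 on GRCm38, stood out in the bulk table. Its 22 variable-exon genes, which share their last exons, each had between 792 and 1374 CPM in the cultures and between 456 and 580 CPM in whole DG, and 21 of them were called, with log2 differences of 0.48 to 1.36 over the 22. In single cells the 21 that were listed summed to 37.4 UMI CPM, against 18192 CPM for the 22 in bulk cultures. Reads of shared exons counted for every gene would give such near-equal values, which was not tested here.

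Xist was detected in 58.4% of the mixed single cells and a Y-linked UMI in 15.9%, and 312 cells (2.09%) had both, where independent detection would give 9.30%. In whole DG of the female, Ddx3y had 21, Kdm5d 10, Eif2s3y 9 and Uty 3 counts, against 883, 540, 476 and 281 in the male, whose library had 10 Xist counts against 8496 in the female. Tnc averaged 2668 CPM in female and 705 CPM in male cultures, with library sizes scaled over the cultures alone. It did not pass the test between sexes (edgeR adjusted p = 0.272), although it was higher in both female cultures than in either male one. Tnc passed with DESeq2 and with no filter on low counts, but not with the other scalings, a stricter filter, limma-voom or all 6 libraries. Fits with a culture left out, which leave a single culture of that sex, are not counted here.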
